A study of Mus musculus with 6 samples.

How the data were processed

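Bulk RNA-seq was made from total RNA of 6 samples labelled NIT-1, 3 given vesicles and 3 given PBS for 16 h, all followed by 8 h of Tm. Per the labels' protocols, the authors removed adaptors and aligned the reads with HISAT2 2.2.1, and per the submitters' processing notes featureCounts 2.0.6 was used. The deposited values are raw counts per gene, with no normalization, and 1 column per sample. The strand setting and the treatment of reads with several positions are not given in the sources used here, so overlapping, antisense and duplicated genes are uncertain. The deposited table also holds gene start, end and length as other values, in bases. The processing notes name the build mm39, but the start and end of 53585 of 54495 gene IDs shared with GENCODE M21 (98.33%) equal those of GRCm38. Coordinates are therefore printed as the deposited table gives them and read as GRCm38.

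The table had 54532 rows, none without a gene identifier, and 28789 genes had at least 1 count. In 27 rows the symbol had been turned into a date, and all 27 were restored from the gene ID. Where a symbol had several IDs, the one with most counts was used. The libraries held 28654248 to 32550268 counts, so that 3 counts, the limit that a count of 0 allows, correspond to 0.0922 to 0.105 CPM, and these limits cover counting error only. The mean chi-square per gene between libraries of one group was 3.71 to 7.78, above sampling noise, against 97.6 to 109 between groups, so all 6 libraries were kept as separate samples. The first principal component held 55.4% of the variance and separated the groups.

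Groups came from the labels. EV_Tm was compared with PBS_Tm by edgeR 4.0.16 in R 4.3.3, with TMM factors, genes kept by filterByExpr, the quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment over 16844 genes. CPM values of tested genes are divided by the TMM-scaled library size, while the limits of 3 counts, the beta-cell genes' 1 CPM minimum and the closing section's counts of genes by CPM use the plain library size; fold changes are EV_Tm minus PBS_Tm on the log2 scale, and the SE was taken from the fold change and its F statistic. The common biological coefficient of variation was 6.05%. Gene lists (33, of which 32 had at least 5 tested genes) were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, and the p adjusted over the lists. Of 20 lists called, 10 were also called with an estimated correlation.

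The design, the lists and the alternatives were fixed before the data were examined. The genes named are the 12 with the largest rise and the 12 with the largest fall among genes that passed, with non-overlapping groups, a mean of at least 1 log2 CPM and a symbol that is not a predicted gene or an identifier, up to 4 genes per list by smallest p, and 10 genes chosen in advance (Xbp1, Hspa5, Atf4, Ddit3, Ins1, Ins2, Atp2a2, Itpr1, Ryr2 and Mcu). The mean was taken over log2 CPM with a prior count of 2, a reading settled after a first fit had been seen. With edgeR's average log2 CPM instead, Klrb1a (log2 fold change 2.49), Mtcl1 (-3.86) and 1700047I17Rik2 (-3.77) would have ranked among the largest changes. Members of a list named because 5 or fewer of them moved or did not pass, the beta-cell genes named for their level, and 4 release channel genes of the ER calcium list were chosen after their values were seen. Results for some genes are not reported here.

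The tests were tried on simulated data with the means, dispersions and library sizes of these 16844 genes and 200 changed genes, 50 at each fold. Over 5 simulations of the comparison, 49.6% of genes changed 1.25-fold were recovered, 54.8% at 1.5-fold, 75.2% at 2-fold and 94.0% at 4-fold, and 6.30% of the calls were false. Only 200 genes were changed, against 7976 that passed in the data, so these shares may not hold for the real comparison. A single simulation was run at first, in which 13 of 147 calls were false (8.84%), above the nominal 5%. The number was then raised to 5, which include the first, with 3.50% to 8.84% false calls. With no change simulated, 0 of 32 lists and 3 genes were called. Genes were drawn independently of each other, so this does not show how the list test behaves where genes are correlated.

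Alternatives were DESeq2's size factors, library size alone, no filter, a stricter filter (1 CPM in 3 libraries), the DESeq2 1.42.0 and limma-voom tests, the replicate number as a block, leaving out each library in turn, a fold minimum of 2, an adjusted p under 0.01, protein-coding genes only, camera with an estimated correlation, and fry.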

Results

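Gene expression was measured by bulk RNA-seq in 6 libraries labelled NIT-1, a mouse insulinoma line used as a model of the pancreatic beta cell. In 3 libraries (EV_Tm) the cells had received extracellular vesicles of human umbilical cord mesenchymal stem cells for 16 h, and in the other 3 (PBS_Tm) they had received PBS. Both groups then had 8 h of Tm, taken here as tunicamycin, an inhibitor of N-linked glycosylation that causes endoplasmic reticulum (ER) stress. One label of the PBS_Tm samples calls them untreated, while their titles and the series' design text place them in the Tm arm, and the latter was followed. No library without Tm was analysed here, so each difference is one between vesicles and PBS under Tm. The libraries held 28654248 to 32550268 counts each (mean 31113592 ± 1420760, SD, n = 6), and 16844 genes were tested.

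The libraries labelled NIT-1 held almost no transcripts of the insulin genes and of many other beta-cell genes in either group, while Cpe and some genes of vesicle docking and fusion were present. The insulin gene Ins2 (chromosome 7, 142678656 to 142743381, coordinates here and below on GRCm38) had 0 counts in all 6 libraries, and Ins1 (chromosome 19, 52264323 to 52265456) had 1 count in all. A count of 0 allows up to 3 counts, or at most 0.105 CPM (counts scaled to library size) in a library, which covers counting error only. Of 46 genes on the list of beta-cell identity and insulin granule genes, 23 lay at or under 3 counts in every library, among them Iapp, Pdx1, Nkx6-1 and Slc30a8, and 7 averaged 1 CPM or more, which were Cpe, Rab3a, Rab27a, Vamp2, Ero1lb, Stx1a and Slc18a2. Of the 12 list genes with enough counts to be tested, Cpe and Rab27a rose, Rab3a and Ero1lb fell and 8 did not pass, with the same counts when adjusted over the list alone. The list as a whole was not called (camera, adjusted p = 0.314). Cpe, the granule carboxypeptidase that trims prohormones, was at 1038 ± 57 CPM in PBS_Tm and 1167 ± 13 in EV_Tm (SD, n = 3 each). Ero1lb, an ER oxidoreductase, was 8.07-fold lower, at 62.2 ± 2.1 CPM in PBS_Tm and 7.70 ± 0.74 in EV_Tm. This gene is also on the list of IRE1-XBP1 targets, a list of ER stress genes described below. Rab27a, a GTPase of granule docking, was 1.68-fold higher. Rab3a passed with a log2 fold change of -0.24 ± 0.07 (SE, edgeR adjusted p = 0.00565), and without EV_Tm replicate 1 it no longer did (adjusted p = 0.066). Members named throughout because 5 or fewer moved or did not pass, and the beta-cell genes named for their level other than Ins1 and Ins2, were chosen after their values were seen.

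The question posed by the design is how vesicle pretreatment changes the response of these cells to ER stress, and the series title names XBP1 and calcium homeostasis. Genes of the unfolded protein response were much lower in EV_Tm. Hspa5 (chromosome 2, 34771970 to 34777547), the main ER chaperone BiP, was at 10012 ± 256 CPM in PBS_Tm and 952 ± 5 in EV_Tm (SD, n = 3 each), a 10.5-fold lower level. It took 0.987% ± 0.023 of all counts in PBS_Tm and 0.0964% ± 0.0004 in EV_Tm. Xbp1 (chromosome 11, 5520659 to 5525893), the transcription factor of the IRE1 branch, was 3.58-fold lower, at 187 ± 5 against 52.2 ± 2.0 CPM. Ddit3, which encodes the stress factor CHOP, was 7.49-fold lower and Atf4, the factor upstream of it, 1.78-fold lower. The edgeR adjusted p was 1.72e-29 for Hspa5, 4.83e-20 for Xbp1, 1.01e-24 for Ddit3 and 4.28e-15 for Atf4, and in each case the 3 values of one group lay apart from the 3 of the other. Gene-level counts do not separate spliced from unspliced Xbp1 transcripts.

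**Figure D1:**
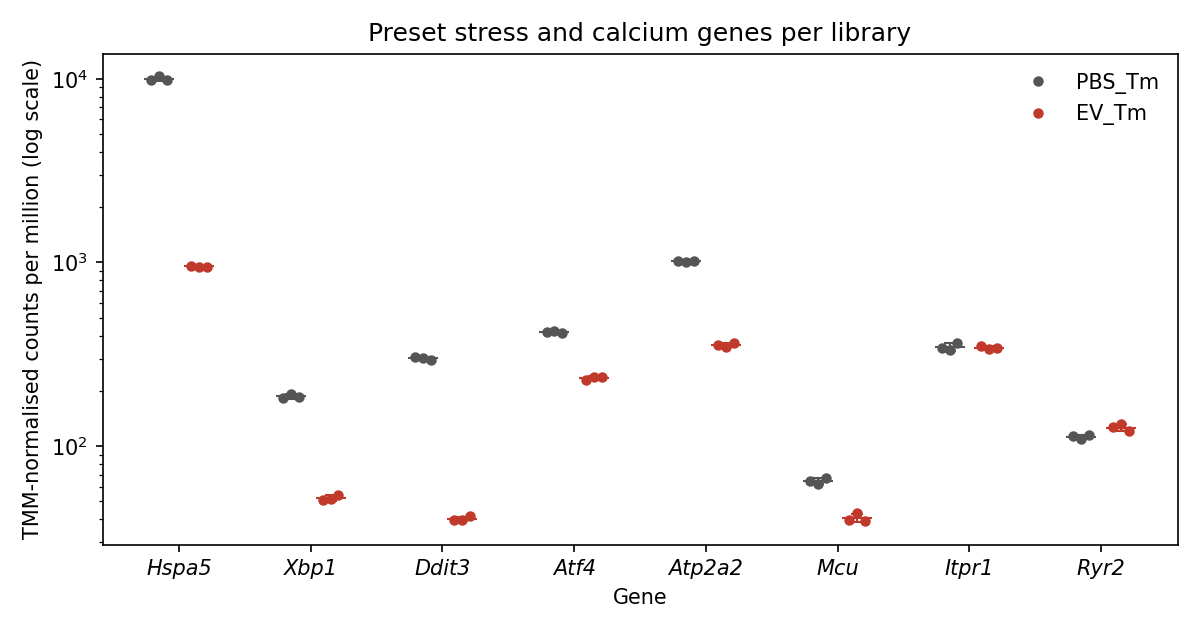
TMM-normalised CPM on a log axis (vertical) for 8 genes (horizontal) chosen in advance, with each library as a point and the mean ± SD (n = 3) as a bar, PBS_Tm in grey and EV_Tm in red. Hspa5, Xbp1, Ddit3, Atf4, Atp2a2 and Mcu lie lower in EV_Tm, Ryr2 slightly higher, and the values of Itpr1 overlap.

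In total 7976 of 16844 genes passed the test between EV_Tm and PBS_Tm (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 3808 higher and 4168 lower in EV_Tm. Most differences were small, with a median absolute log2 fold change of 0.40 among the genes that passed. With a fold change of at least 2 as well, 1006 genes remained, of which 553 were higher and 453 lower, and at 4-fold there were 65 higher and 95 lower. The values of the groups did not overlap in 54.5% of the tested genes, where chance gives 10%. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

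All the stress branches were lower together. On the list of ATF6 targets and ER chaperones, 24 of 26 tested genes fell and Atf6b and Cdnf did not pass, with a median log2 fold change of -2.15 (25 fell when adjusted over the list alone; camera adjusted p = 7.86e-219). The members of this list took 2.88% ± 0.05 of all counts in PBS_Tm and 0.492% ± 0.004 in EV_Tm (SD, n = 3 each). Pdia4, an ER disulfide isomerase, fell by 3.12 ± 0.04 on the log2 scale and Hyou1, a large ER chaperone, by 2.91 ± 0.04 (SE). Of 52 genes on the list of IRE1-XBP1 targets, 47 fell, only Spcs1 rose and 4 did not pass (median -1.07; 49 fell when adjusted over the list alone; camera adjusted p = 2.27e-138). Creld2, an ER-resident chaperone-like protein, was 20.1-fold lower in EV_Tm, at 470 ± 26 CPM in PBS_Tm and 23.4 ± 1.1 in EV_Tm (SD, n = 3 each). Dnajc3, an ER co-chaperone, was 7.83-fold lower. Creld2 and Dnajc3 are both also on the ATF6 and chaperone list, which shares 6 genes with the IRE1-XBP1 list. Camera with an estimated correlation gave an adjusted p of 0.00154 for the ATF6 list and 0.00154 for the IRE1-XBP1 list. The 42 XBP1 targets on none of the PERK, ATF6 or degradation lists, a subset formed after the data were seen, had a median of -0.86, and 37 of them fell.

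The PERK-ATF4-CHOP list had 20 of 23 genes lower and Vldlr, Ero1l and Nfe2l2 higher (median -0.83; the same counts adjusted over the list alone; camera adjusted p = 9.38e-33). Trib3, a pseudokinase induced by CHOP, was at 267 ± 16 CPM in PBS_Tm and 60.3 ± 3.4 in EV_Tm (SD, n = 3 each). Ppp1r15a, which directs the dephosphorylation of eIF2-alpha, was 4.41-fold lower, and Nupr1, a stress-induced chromatin factor, 4.84-fold lower. Of 33 genes for amino acid synthesis, transport and tRNA charging, many of them ATF4 targets, 31 fell and Slc1a5 and Mars did not pass (median -0.72; the same counts adjusted over the list alone; camera adjusted p = 4.57e-35). Wars, the tryptophanyl-tRNA synthetase, was 2.44-fold lower and the mitochondrial folate enzyme Mthfd2 2.08-fold lower. For the PERK and the amino acid lists, camera with an estimated correlation gave an adjusted p of 0.0216 each.

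Genes of ER quality control moved the same way. In ER-associated degradation, 23 of 31 genes fell and 8 did not pass (median -0.44; 25 fell when adjusted over the list alone; camera adjusted p = 1.30e-31). Herpud1, which organises the degradation complex, was 9.67-fold lower, Sel1l 5.92-fold lower and its ubiquitin ligase partner Syvn1 4.97-fold lower. The degradation list shares 3 genes with the ATF6 and chaperone list, Herpud1 and Sel1l among them, and 4 with the IRE1-XBP1 list. It was not tested without them. On the list of N-glycosylation and tunicamycin uptake, the only uptake gene, Mfsd2a, had 6 counts over all libraries and was not tested, a gene named after its counts were seen. Of the 41 other genes 25 fell, Dpm1, Dpm3, Dad1 and Ost4 rose, and 12 did not pass (median -0.43; the same counts adjusted over the list alone; camera adjusted p = 3.43e-18). The mannosyltransferase Alg12 was 5.13-fold lower and Rpn1, a subunit of the oligosaccharyltransferase, 3.30-fold lower. With an estimated correlation, the camera adjusted p was 0.0134 for the degradation list and 0.00492 for the N-glycosylation list.

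Calcium handling genes of the ER were lower on balance. On the list of ER calcium stores, 17 of 33 genes fell, 7 rose and 9 did not pass (median -0.19; the same counts adjusted over the list alone; camera adjusted p = 9.09e-10). Atp2a2 (chromosome 5, 122453513 to 122502225), the SERCA2 pump that fills the ER with calcium, was 2.86-fold lower, at 1016 ± 7 CPM in PBS_Tm and 355 ± 9 in EV_Tm (SD, n = 3 each). Its relative Atp2a3 was 10.2-fold lower from a low level of 13.3 ± 1.3 CPM in PBS_Tm. The calcium-binding chaperone Calr was 4.30-fold lower and Nucb2, a calcium-binding secretory protein, 6.12-fold lower. The list shares Calr, Canx and Selenok with the ATF6 and chaperone list and Wfs1 with the IRE1-XBP1 list, all of which fell. It was not tested without them. The 6 tested genes for release channels went different ways. The ryanodine receptor gene Ryr1 was 2.48-fold higher, at 55.1 ± 2.8 CPM in PBS_Tm and 137 ± 4 in EV_Tm (SD, n = 3 each, edgeR adjusted p = 1.52e-16), and the inositol trisphosphate receptor gene Itpr2 fell by 0.47 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 1.44e-06). Itpr1 had a log2 fold change of -0.01 ± 0.04 (SE, edgeR adjusted p = 0.802), and Ryr2 one of 0.17 ± 0.05 (SE, edgeR adjusted p = 0.00502), a call lost without EV_Tm replicate 2 (adjusted p = 0.0655). Itpr3 and Ryr3 did not pass. Of these 6, all but Itpr1 and Ryr2 were named after their values were seen. Camera with an estimated correlation gave an adjusted p of 0.0216 for the ER calcium list.

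For mitochondrial calcium and ER contacts, 19 of 31 genes fell, Vdac1, Vdac2, Fundc2, Bcap31 and Ppif rose and 7 did not pass (20 fell when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.103). Mcu (chromosome 10, 59446984 to 59616692), the pore of the mitochondrial calcium uniporter, was 1.59-fold lower, at 64.6 ± 2.4 against 40.7 ± 2.2 CPM (SD, n = 3 each), and the mitochondrial chaperone Hspa9 was 1.70-fold lower. Vdac1, the outer membrane channel, was 1.35-fold higher. At the plasma membrane 13 of 36 genes rose, 9 fell and 14 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.107). Among these the potassium channel gene Kcnk3 was 2.86-fold higher and Rcan1, an inhibitor of calcineurin, 2.42-fold lower.

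Mitochondrial respiratory genes were modestly higher in EV_Tm. Of 77 nuclear-encoded genes of oxidative phosphorylation, 49 rose, Uqcrc2 and Cycs fell and 26 did not pass (median 0.23; the same counts adjusted over the list alone; camera adjusted p = 1.71e-08). With an estimated correlation between genes this list was not called (adjusted p = 0.262 with an estimated correlation). Uqcrh, a subunit of complex III, was at 22.4 ± 0.6 CPM in PBS_Tm and 84.8 ± 2.0 in EV_Tm (SD, n = 3 each), and Cox6b1 and Sdhd were 1.86-fold and 1.87-fold higher. Of 12 mitochondrially encoded subunits 9 rose and mt-Nd3, mt-Nd4l and mt-Nd6 did not pass (median 0.30; 10 rose when adjusted over the list alone; camera adjusted p = 0.00309, and adjusted p = 0.322 with an estimated correlation). Transcripts of the mitochondrial genome took 2.51% ± 0.08 of counts in PBS_Tm and 2.93% ± 0.05 in EV_Tm. Genes of mitochondrial dynamics, mitophagy and proteostasis went both ways, with 13 of 40 higher, 15 lower and 12 not passing, the same adjusted over the list alone. Their median was -0.02, their mean 0.01, and camera gave an upward direction without a call (adjusted p = 0.607).

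**Figure D2:**
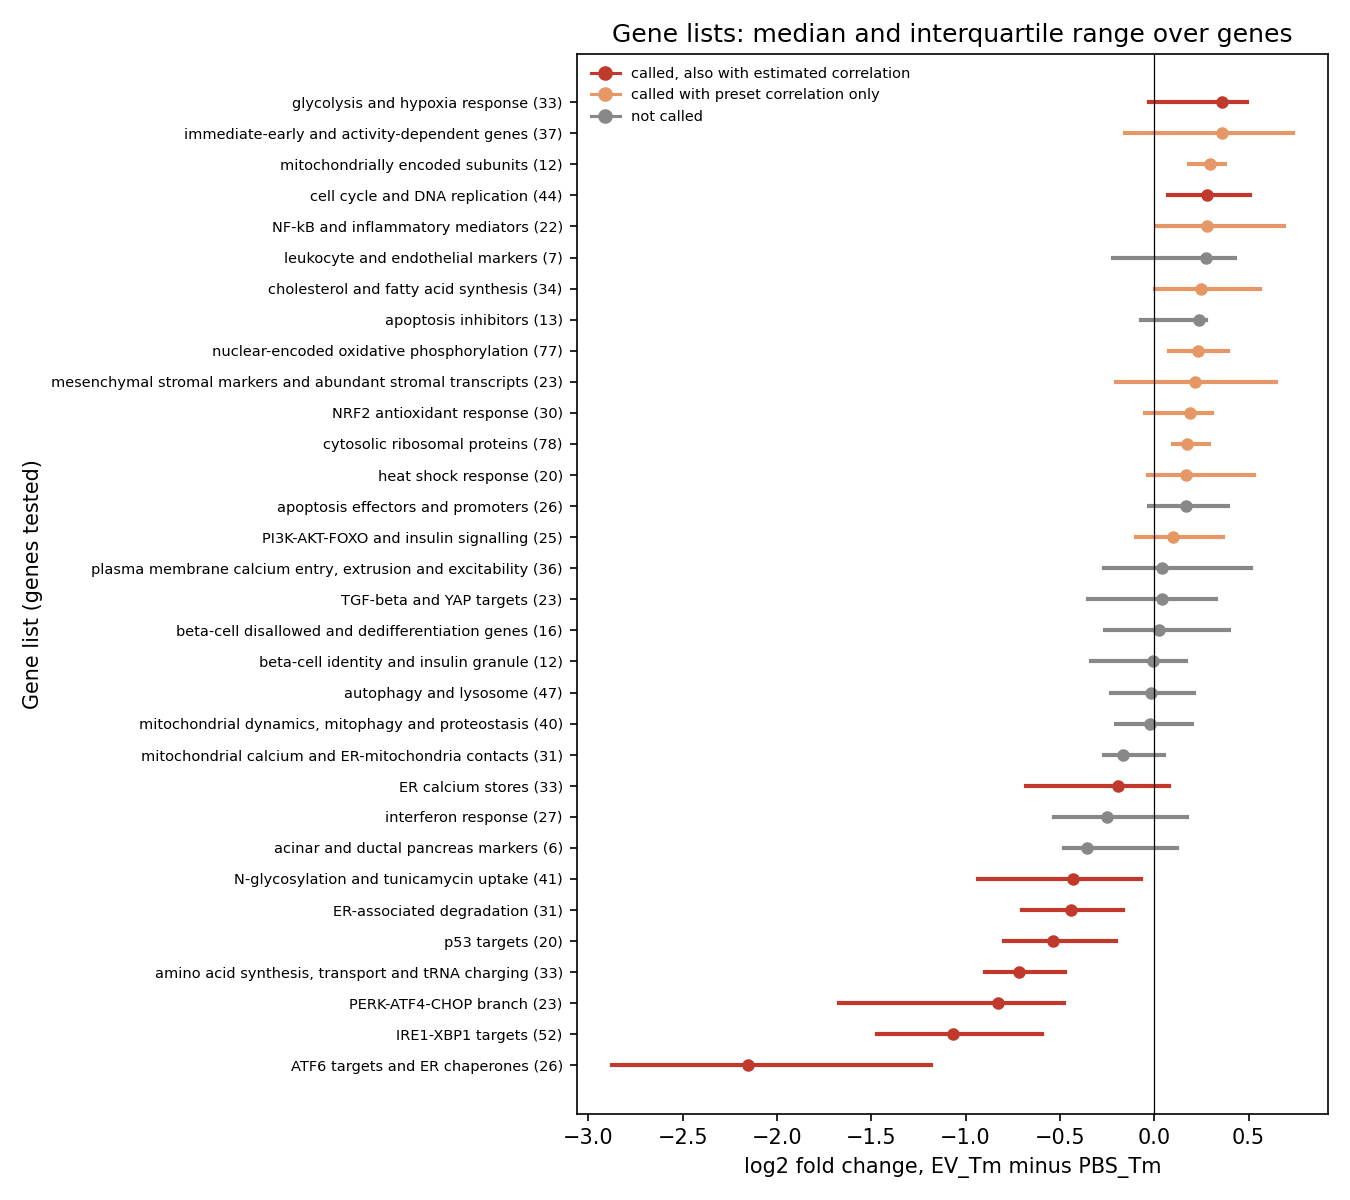
Median (point) and interquartile range (line) of log2 fold change, EV_Tm minus PBS_Tm, over the tested genes of 32 lists fixed in advance, with the number of genes in parentheses. The ATF6 and chaperone list has the lowest median, -2.15; red marks lists called by camera with both correlations, orange those called with the preset correlation only, and grey those not called.

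Neither list of cell death genes was called. Of 26 apoptosis effectors and promoters, 12 rose, Bbc3 and Tnfrsf10b fell and 12 did not pass (camera adjusted p = 0.0711), and of 13 inhibitors 8 rose, Bcl2, Bcl2l2 and Cflar fell and Bag3 and Hspb1 did not pass (camera adjusted p = 0.134). Adjusted over each list alone, the promoters had the same counts and 9 inhibitors rose. Tnfrsf10b, the death receptor DR5, was 1.45-fold lower, Bmf 1.64-fold higher and the BCL2-family survival gene Mcl1 1.36-fold higher. Of 20 p53 targets 15 fell, Sesn1 and Trp53 rose and 3 did not pass (median -0.54; 4 rose and 15 fell when adjusted over the list alone; camera adjusted p = 9.09e-10), among them Gdf15, a stress cytokine, which was 2.29-fold lower. This list shares 4 genes with the PERK list. Its camera adjusted p with an estimated correlation was 0.0134.

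The lists of cell cycle, glycolysis, cholesterol and ribosomal protein genes had more members higher than lower in EV_Tm. In cell cycle and DNA replication 29 of 44 genes rose, Ccnd2, Cdc20, Cdc25c, Cdc6 and Rfc4 fell and 10 did not pass (median 0.28; 31 rose when adjusted over the list alone; camera adjusted p = 5.48e-08), with the ribonucleotide reductase gene Rrm2 1.90-fold and the replication helicase gene Mcm5 1.73-fold higher. In glycolysis and hypoxia 22 of 33 rose, Hk2, Pfkfb3, P4ha2, Ddit4 and Hif1a fell and 6 did not pass (median 0.36; the same counts adjusted over the list alone; camera adjusted p = 1.34e-06), with Pgam1 1.71-fold and Ldha 1.47-fold higher. Cholesterol and fatty acid synthesis had 19 of 34 higher, Mvd, Ebp and Sc5d lower and 12 not passing (median 0.25; the same counts adjusted over the list alone; camera adjusted p = 1.15e-04, and adjusted p = 0.0802 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, was 1.69-fold higher. The camera adjusted p with an estimated correlation was 0.0134 for the cell cycle list and 0.0251 for the glycolysis list. Of 78 cytosolic ribosomal protein genes 55 rose, Rps27a fell and 22 did not pass (median 0.17; 56 rose when adjusted over the list alone; camera adjusted p = 9.38e-07, and adjusted p = 0.380 with an estimated correlation). Rpl37a was 2.05-fold higher. Random lists matched on gene length and expression had a median of 0.16 for this list and 0.05 for the oxidative phosphorylation list, a comparison chosen after the medians were seen.

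Among genes with a mean of at least 1 log2 CPM, those with the largest rises were of mixed kinds. Genes under that minimum, some of them with larger fitted changes, were not ranked. Hspa8, the constitutive cytosolic chaperone, went from 342 ± 2 CPM in PBS_Tm to 1381 ± 14 in EV_Tm (SD, n = 3 each). The chemokine gene Cxcl1 was 5.87-fold higher, the extracellular matrix gene Fbln2 5.12-fold, the cytoskeletal gene Add2 5.29-fold, Rasal1, a Ras GTPase-activating protein, 4.76-fold, and Cyp1b1, a cytochrome P450, 7.03-fold. Lrrc4, Tmprss13, Bpifa2 and Exoc3l2 were between 3.61-fold and 7.30-fold higher. Of the genes ranked, Srp54b had the largest fitted rise, 12.7-fold, but its EV_Tm libraries varied (9.89 ± 6.63 CPM, SD, n = 3) and it has close copies, Srp54a and Srp54c, so the value is uncertain. Among the largest falls of ranked genes outside the ER lists were Mcf2l (265 ± 1 CPM in PBS_Tm and 22.1 ± 1.0 in EV_Tm), the secretory cell transcription factor Bhlha15 (13.9-fold lower) and Zcchc12 (8.40-fold lower). Sdf2l1, an ER protein, was 12.4-fold lower.

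Signalling and inflammatory lists rose with the preset correlation but not with an estimated one. Of 37 immediate-early genes 19 rose, 7 fell and 11 did not pass (median 0.36; 20 rose and 8 fell when adjusted over the list alone; camera adjusted p = 6.37e-05, and adjusted p = 0.198 with an estimated correlation), with Egr1 2.93-fold and Fos 3.56-fold higher. Of 22 NF-kB and inflammatory genes 11 rose, Rela, Ptgs2 and Csf1 fell and 8 did not pass (median 0.28; the same counts adjusted over the list alone; camera adjusted p = 2.47e-05, and adjusted p = 0.0605 with an estimated correlation). Nfkbia, the NF-kB inhibitor, was 1.80-fold higher. The heat shock list had 10 of 20 higher, Hspa4l, Hsf1, Hsf2 and Chordc1 lower and 6 not passing (13 rose when adjusted over the list alone; camera adjusted p = 3.51e-05, and adjusted p = 0.153 with an estimated correlation), and Hsph1 was 1.75-fold higher.

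The antioxidant and insulin signalling lists had members on both sides. NRF2 antioxidant genes had 18 of 30 higher and Keap1, Slc7a11, Cat, Abcc1 and Osgin1 lower, with 7 not passing (median 0.19; the same counts adjusted over the list alone; camera adjusted p = 0.0251, and adjusted p = 0.398 with an estimated correlation), and without PBS_Tm replicate 3 the call was lost (adjusted p = 0.05945). Slc7a11, the cystine transporter and also an ATF4 target, was 2.03-fold lower and Prdx1 1.49-fold higher. PI3K-AKT-FOXO and insulin signalling had 11 of 25 higher and Tsc1, Rheb and Gsk3b lower, with 11 not passing (median 0.10; 11 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.0120, and adjusted p = 0.128 with an estimated correlation), with Sgk1 1.75-fold higher.

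Markers of other cells were examined as well, since the vesicle donors are human stromal cells. The counts are on mouse genes, so they cannot tell RNA carried by the human vesicles from RNA of the treated cells. Of 23 tested mesenchymal stromal genes 13 rose, Col1a1, Pdgfrb and Fbn1 fell and 7 did not pass (13 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.0158, and adjusted p = 0.153 with an estimated correlation). Col6a1 was 1.69-fold and S100a6 1.90-fold higher, and the pericyte receptor gene Pdgfrb was 2.91-fold lower. Of 6 acinar and ductal genes Cela1 and Spp1 rose, Bhlha15 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.759). Of 7 leukocyte and endothelial genes Cd68 and Fcer1g rose, Pecam1 fell and 4 did not pass (1 rose when adjusted over the list alone; camera adjusted p = 0.367). Other islet hormone genes had 3 tested members, too few for a list test, of which Hhex fell. The calls of Cd68, Cela1, Hhex and Pecam1 depended on single libraries and on the processing. All were lost without EV_Tm replicate 2 and without EV_Tm replicate 3, those of Cd68 and Cela1 also without PBS_Tm replicate 2, that of Cela1 without PBS_Tm replicate 3 and that of Hhex without PBS_Tm replicate 1. Without EV_Tm replicate 2 their adjusted p was 0.249 for Cd68, 0.102 for Cela1, 0.0793 for Hhex and 0.0661 for Pecam1. With all libraries kept, library size alone as the scaling ended the calls of Hhex (adjusted p = 0.0523) and Pecam1 (adjusted p = 0.0571), and that of Cd68 was lost with DESeq2 (adjusted p = 0.105) and limma-voom (adjusted p = 0.0591).

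The lists that were not called had members on both sides. The list of disallowed genes, as it is called below, had 16 tested members, either normally disallowed in beta cells or linked to their dedifferentiation. Of these 7 rose, Rest, Hk2, Oat, Igfbp4 and Acot7 fell and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0554). Hes1 was 3.14-fold higher. Of 27 interferon response genes Bst2, Dhx58 and B2m rose, 11 fell and 13 did not pass (4 rose and 12 fell when adjusted over the list alone; camera adjusted p = 0.607), with Oas1b 2.65-fold lower. Autophagy and lysosome had 17 of 47 higher, 16 lower and 14 not passing (18 and 17 when adjusted over the list alone; camera adjusted p = 0.746), with the cargo receptor gene Sqstm1 1.64-fold lower. TGF-beta and YAP targets had 9 of 23 higher, 6 lower and 8 not passing (10 and 7 when adjusted over the list alone; camera adjusted p = 0.535), with Axl 1.62-fold higher and Id3 2.04-fold lower.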

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

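Every alternative here was planned before the data were examined. The count of 7976 genes lay between 7080 and 8013 under the other scalings, filters and tests, with protein-coding genes only and without any 1 library, and at an adjusted p under 0.01 it was 6300. With a fold change of at least 2, 1006 remained (553 higher, 453 lower), because that minimum removes small changes. Without any 1 library there were 3277 to 3616 genes higher and 3785 to 4092 lower. With library size alone as the scaling, 53.8% of calls were higher against 47.7%. The replicate number as a block gave 7737 genes and changed no list's call; samples with equal numbers did not deviate together (correlations -0.04, 0.02 and -0.01), and only replicate 2 of each group correlated best with its own number. No named gene that was called changed direction. The calls of Cd68, Cela1, Hhex, Pecam1, Rab3a and Ryr2 were lost under at least 1 alternative, and the cause was not tested. Depth limits the beta-cell genes, where 3 counts correspond to at most 0.105 CPM.

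Camera with an estimated correlation left 10 of 20 lists. The adjusted p of those it lost was 0.2618 for oxidative phosphorylation, 0.3216 for mitochondrially encoded subunits, 0.1534 for the stromal and the heat shock lists, 0.06047 for NF-kB, 0.3976 for NRF2, 0.08017 for cholesterol and fatty acid synthesis, 0.1975 for immediate-early genes, 0.1276 for PI3K signalling and 0.3801 for ribosomal proteins. Without any 1 library 19 to 20 lists were called, and the adjusted p of NRF2 ranged from 0.01616 to 0.05945. Without a filter, mitochondrial calcium (0.01246), apoptosis promoters (0.04337) and disallowed genes (0.02552) were called as well, the last also with library size alone (0.03493). The fry test, which does not compare a list with other genes, called 29 lists for one direction and 32 for either. Of lists that camera did not call, its adjusted p for one direction and for either was 0.0004529 and 8.192e-07 for mitochondrial calcium, 0.00562 and 3.311e-07 for plasma membrane calcium, 0.001727 and 2.084e-07 for apoptosis promoters, 0.0007933 and 6.18e-06 for inhibitors, 0.0005012 and 1.16e-06 for beta-cell identity, 1.823e-05 and 2.692e-06 for disallowed genes, 0.01074 and 0.0003062 for leukocyte and endothelial markers, 0.0005839 and 2.326e-05 for interferon, and 0.003697 and 8.73e-07 for TGF-beta and YAP. For either direction alone it was 8.192e-07 for mitochondrial dynamics, 6.394e-06 for acinar and ductal markers and 2.231e-07 for autophagy. The causes of these differences were not tested.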

Other observations

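The tests in this part were chosen after the results were seen, except the comparison of the respiratory and ribosomal lists with matched random lists, which was set before its outcome was known but after a trend with gene length had been noticed.

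Some genes outside the lists of the report also differed. Genes of steroid hormone synthesis, on a list of 19 cut down after the data were seen from a longer lookup of genes of several tissues, were measured as well, and 11 of them reached 1 CPM in every library. Cyp11a1, the side-chain cleavage enzyme, was at 261 ± 13 CPM in PBS_Tm and 593 ± 7 in EV_Tm (SD, n = 3 each, log2 fold change 1.18 ± 0.04, SE, edgeR adjusted p = 9.51e-18), and Nr5a1, the steroidogenic transcription factor SF-1, at 336 ± 21 and 606 ± 6 (log2 fold change 0.85 ± 0.04, edgeR adjusted p = 1.45e-14), while Star did not pass (0.03 ± 0.08). Of 12 tested genes of this list 8 rose and 1, Akr1b7, fell. Small nucleolar RNA genes had a median log2 fold change of 0.63 over 92 genes, of which 21 rose and 71 did not pass, and antisense genes one of 0.27 over 748, of which 128 rose and 45 fell, where the strand setting is not known.

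The near absence of transcripts of 23 genes on the beta-cell list, the insulin genes and Pdx1 among them, is the first pattern weighed. Reads lost in counting to overlapping genes or annotated pseudogenes do not account for all of it, since 16 of the 23 genes at or under 3 counts have neither. Pdx1 and Iapp overlap another gene and are not among the 16. A loss of reads shared between similar functional genes, such as Ins1 and Ins2, was not tested. Whether ER stress silenced the beta-cell genes stays open: of 25 genes silent in PBS_Tm, 0 exceeded 3 counts in every EV_Tm library, where the stress genes were lower, but no library was without Tm. Whether cells of another line were in place of NIT-1 stays open as well, since the 11 of 19 adrenocortical genes that reached 1 CPM in every library are on a list put together after their levels had been seen, so that their number decides nothing, and Mc2r, Nr0b1 and Lhcgr of the same list had 0 counts. A loss of identity within NIT-1 was not tested.

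The much lower stress genes of EV_Tm are the second pattern. The choice among 3 library scalings does not account for it. The median of the ATF6 and chaperone list stayed at or below -2.112 under TMM factors, DESeq2's size factors and library size alone. The TMM factors lay between 0.983 and 1.016, so these scalings could differ little. All 3 are relative to the counts of the libraries, so a change in total RNA per cell was not tested. A weaker Tm exposure of the EV_Tm libraries cannot be told apart from an effect of the vesicles on the response, since both would lower this list (median -2.152) and no library without Tm or measure of exposure was analysed here. For that reason the biological explanation, a milder stress response after vesicles, stays a hypothesis. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many called genes, 7976 against at most 0 in the other splits by edgeR (at an unadjusted p under 0.05, 8900 against 172 to 268). Every other split mixed the groups on each side, which puts the group difference into the spread. Since 10 splits are also too few for a share under 0.05, the splits decide nothing about chance.

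The modest rise of respiratory and ribosomal protein genes is the third pattern. Both lists hold short genes, with a median deposited gene length of 1718 and 1754.5 bases against 4336 for all tested protein-coding genes. A trend with gene length and expression level may account for the ribosomal list, whose median of 0.17 lay at percentile 79.56 of 10000 random lists matched on both (matched median 0.16). It does not account for all of the rise of the oxidative phosphorylation list, whose median of 0.23 lay at percentile 100, above the matched range of -0.04 to 0.13. Random lists treat genes as independent, which correlated respiratory genes are not, so a shared biological cause was not shown.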
